A study of Mus musculus with 7 samples.

How the data were processed

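RNA from mouse hearts was measured on 7 spotted cDNA arrays with a Cy3 and a Cy5 channel. Each array carried RNA of BcA70, a recombinant congenic strain bred from C57BL/6 and A/J, against RNA of C57BL/6. The infected group held 4 arrays of hearts taken 24 h after injection of Candida albicans blastospores into the tail vein, and the uninfected group held 3. The design text states 4 biological replicates per strain for either condition; a further uninfected array is not analysed here. Groups were taken from the source names and titles, and replicate numbers only follow the order of the samples. BcA70 was in Cy5 on infected replicates 2 and 3 and on uninfected replicates 1 and 3, and in Cy3 on the others. Uninfected replicate 3 came from females and the other arrays from males, per the labels. For infected replicate 2 the labels disagree: its source name gives C57BL/6 in the second channel, while its characteristics give BcA70 there, with an RNA name that also stands on infected replicate 1. The labels name separate RNAs otherwise and do not state whether an RNA came from a single animal, so p-values measure the spread between these samples.

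The deposited values are log ratios, read here as log2. Per the labels, the authors scanned the slides with a ScanArray scanner, extracted intensities with QuantArray 3 and analysed them in GeneSpring 7, and per the design text they applied a dye swap correction and an intensity-dependent normalization. How replicate spots, background and flagged spots were treated is not given in the sources used here. The base of the logarithm is not stated. The range of the values was too wide for log10, and log2 against natural log could not be settled, so every fold below would be larger if the base were e. The direction is not stated outright either. It was taken as BcA70 over C57BL/6, which is likely because the design text names C57BL/6 as the control. Correlations between arrays do not settle it: pairs of opposite dye orientation ranged from -0.119 to 0.456 in the infected group and were -0.203 and -0.00471 in the uninfected group, where the pair of the same orientation was at 0.279. The value table held no intensities, so signal over background is unknown for every probe, and the number of arrays limits the precision. An intensity-dependent normalization sets the typical ratio of an array to 0, so each difference is relative to the average probe.

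The table held 15247 probes. The platform annotation gave 8077 of them exactly 1 gene symbol, 369 several and 6801 none. Of the probes with 1 symbol, 8058 were matched by Entrez identifier to a RefSeq gene table of the GRCm38 assembly family, and 0 symbols needed an update. No gene was named from a probe with several symbols, and no coordinates were used beyond which genes neighbour each other.

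Values were used as deposited, without further centring. A probe entered with at least 3 infected and 2 uninfected values, which left 15246 probes. A single limma 3.58.1 fit (lmFit and eBayes, R 4.3.3) over all 7 arrays gave a mean log2 ratio per group, so that both groups shared the estimate of the spread. Each group mean was tested against 0, and infected minus uninfected tested whether the strain difference changed with infection. Tests were two-sided, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. Values of genes are means ± SD over arrays.

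Before the data were examined, 28 gene lists were fixed. After averaging the probes of each symbol, 6378 genes had a value on every array, and the 25 lists with at least 5 such genes were tested with limma's camera at a preset inter-gene correlation of 0.01. The 75 list tests were adjusted together. The lists of T, B and NK lymphocyte markers, adipocyte markers and markers of skeletal muscle, lung and liver had too few measured members. Counts of list members come from the gene-level fit, and values of single genes from the gene's probe with the smallest p. Named genes followed a rule fixed at the same time: the 10 higher and 10 lower genes with the largest mean among those that passed and had the same sign on every array (for the difference, no overlap of the groups), filled to 5 by smallest p, 16 genes chosen by name, and, of each list that passed or was described, the 2 members with the smallest p in each direction. Of the 16 genes, Hc, Nppa, Myh7, Acta1, Pdk4, Cd36, S100a8, Saa3, Timp1 and Serpina3n had no probe carrying their symbol alone. Describing the sarcomere, macrophage and interferon lists, which did not pass, was chosen after their values were seen.

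The fit was tested on simulated data with 50 probes shifted by each of the amounts below, all in the same data. The noise was independent and normal, with a single SD per probe for both groups and neither dye effects nor correlation between probes. Recovery on the real arrays may therefore differ from these counts. In infected hearts 24 of 50 probes shifted by 0.5 were recovered, 42 of 50 at 1, 48 of 50 at 1.5 and 50 of 50 at 2. In uninfected hearts the counts were 16, 43, 49 and 49, and for infected minus uninfected 5, 27, 44 and 49. Unshifted probes called numbered 7 in infected hearts, 10 in uninfected hearts and 5 for infected minus uninfected. Alternatives were median centring, scaling the arrays to equal spread, a dye term, turning the sign of the arrays with BcA70 in Cy3, stricter and looser filters on missing values, gene-level values, array weights, robust eBayes, fits on a group's own arrays, infected replicates 1 and 2 averaged, an estimated inter-gene correlation, camera on ranks or probes, and leaving out each array. Figures were drawn with matplotlib 3.10.9.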

Results

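The 7 arrays compared the hearts of BcA70 and C57BL/6 mice, 4 arrays after Candida albicans infection and 3 without it. The series asks about differing susceptibility of mouse strains to this fungus. Between 15189 and 15245 of the 15247 probes had a value on an array. Each array's median log2 ratio lay between -0.0226 and 0.019, and the SD of the ratios ranged from 0.248 to 0.425 on infected arrays and from 0.179 to 0.303 on uninfected arrays. Across probes, which are not independent replicates, pairs of infected arrays correlated at a median r of 0.357, with a range from -0.119 (replicates 1 and 2) to 0.456. Pairs of uninfected arrays ranged from -0.203 to 0.279. Positive values below mean a higher level in BcA70, which is the likely but not stated direction, and folds assume log2, a base that no source states.

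In infected hearts, the 10 named genes with the largest positive strain difference included Lcn2, Hmox1, Gadd45g, Socs3 and Nppb. Lcn2, which encodes an iron-siderophore-binding protein of the innate immune defence, was 2.15 ± 1.65 higher (SD, n = 4), a 4.43-fold difference, or 8.57-fold if the deposited base were e. Its values on the 4 arrays were 0.56, 3.40, 0.91 and 3.73. Hmox1, the inducible heme oxygenase, was 1.76 ± 0.13 higher, Gadd45g, a stress-induced growth arrest gene, 1.93 ± 0.60 and Socs3, a feedback inhibitor of cytokine signalling, 1.80 ± 0.49. Nppb, which encodes the natriuretic peptide released by strained heart muscle, was 1.83 ± 0.43 higher. The other genes with the largest positive differences were Cdk8, a kinase of the Mediator complex, at 1.89 ± 0.50, Id2, an inhibitor of helix-loop-helix transcription factors, at 1.80 ± 0.64, Mir22hg, the host transcript of a microRNA, at 1.73 ± 0.79, S100a9, a calcium-binding protein abundant in neutrophils, at 1.73 ± 0.44, and Hdc, the enzyme that makes histamine, at 1.62 ± 0.39. Adjusted p for these 10 genes ran from 7.31e-06 (Hmox1) to 0.0249 (Lcn2), and each was higher on all 4 arrays, which the rule for naming them required. Id2 has 2 probes, and its value is that of the probe with the smaller p. Over the alternatives other than turned Cy3 arrays it fell as low as 0.97, and it passed in each (limma adjusted p at most 0.00844).

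Of the 10 named genes with the largest negative differences, 5 encode a collagen or chaperones and folding enzymes of the endoplasmic reticulum. Col3a1, a fibrillar collagen, was at -1.92 ± 0.69 and Serpinh1, the chaperone of collagen, at -1.52 ± 0.15. The endoplasmic reticulum chaperones Hsp90b1 and Hspa5 were at -1.75 ± 0.32 and -1.37 ± 0.33, and the disulfide isomerase Pdia6 at -1.20 ± 0.32. Gja1, the main gap junction protein of the ventricle, was at -1.35 ± 0.70 and Mgp, an inhibitor of calcification, at -1.19 ± 0.60. Vta1, a factor of endosomal sorting, was at -1.59 ± 0.58, the transcription factor Zeb2 at -1.17 ± 0.30 and the uncharacterised 4921507G05Rik at -1.43 ± 0.58. Adjusted p for these 10 genes ran from 8.8e-05 (Hsp90b1) to 0.00789 (Gja1). Vta1 also has 2 probes. Over the alternatives other than turned Cy3 arrays its value came as near 0 as -0.89, and it passed in each (limma adjusted p at most 0.0142).

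**Figure D1:**
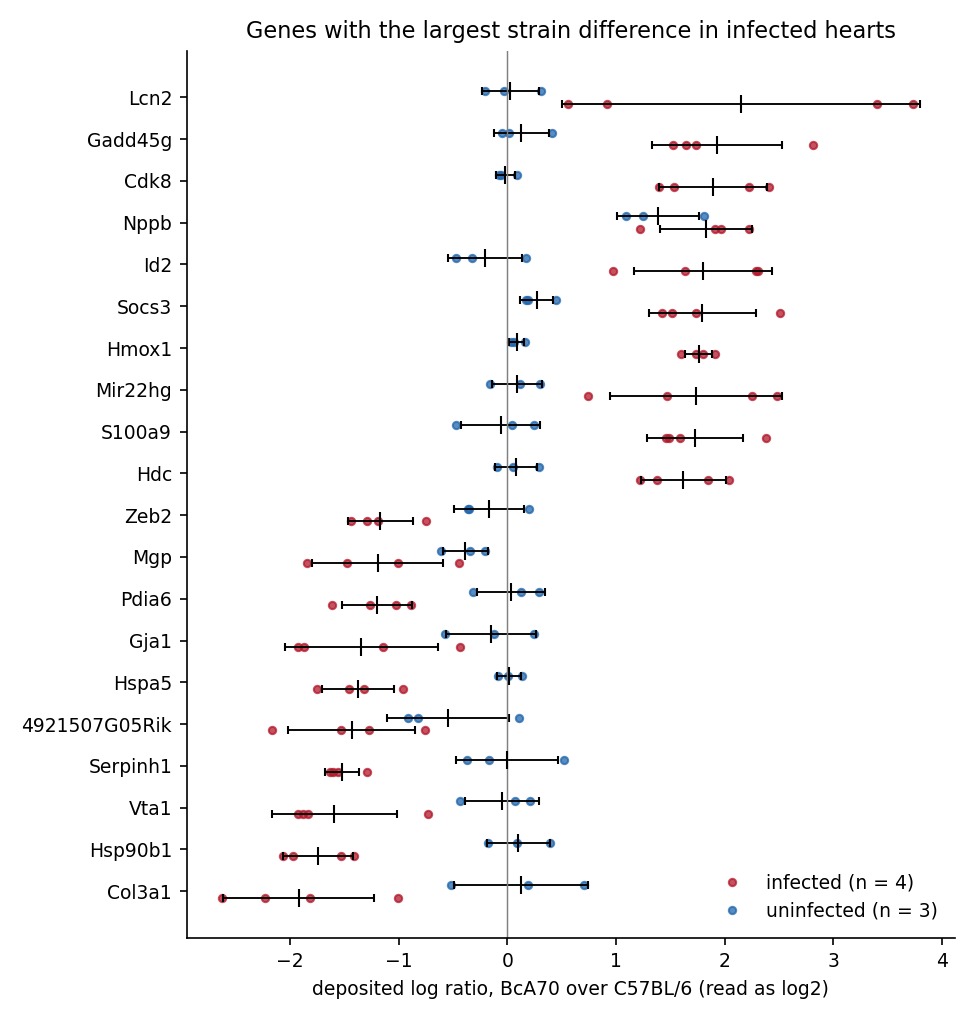
Deposited log ratio of BcA70 over C57BL/6, read as log2 (x axis), for the 20 named genes with the largest strain difference in infected hearts (y axis); points are arrays, bars the mean ± SD, red 4 infected and blue 3 uninfected arrays. Of the genes shown, Nppb also had a high uninfected mean, 1.38, while Lcn2 spread from 0.56 to 3.73 in infected hearts.

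Of the lists fixed in advance, 11 passed in infected hearts. Among 12 acute-phase and injury genes, 5 were higher, 0 lower and 7 did not pass, with 6 higher when adjusted over the list alone. The list mean was 0.73 ± 0.21 (adjusted p = 1.18e-07, and adjusted p = 0.0802 with an estimated correlation). Cp at -0.02 and F3 at -0.0025 were its members below 0. Among 6 measured inflammatory cytokine and feedback genes, 3 were higher and 3 did not pass, with 3 higher adjusted over the list alone. Its mean was 0.71 ± 0.26 (adjusted p = 0.00173, and adjusted p = 0.125 with an estimated correlation). Nfkbiz, a nuclear regulator of inflammatory genes, was 0.85 ± 0.59 higher beside Socs3, and Cxcl12 was at -0.19 ± 0.16.

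Neutrophil markers were split. Of 7, 4 were higher, 1 was lower and 2 did not pass, with the same counts of 4 and 1 adjusted over the list alone (mean 0.57 ± 0.13, adjusted p = 0.00023, and adjusted p = 0.137 with an estimated correlation). S100a9 and Hdc were higher, whereas Lyz2, a lysozyme of neutrophils and macrophages, was at -0.89 ± 0.18 (adjusted p = 0.00206) and Stfa1 at -0.05 ± 0.12. The 14 monocyte and macrophage markers did not pass as a list (adjusted p = 0.265), with 2 members higher and 1 lower, or 5 and 2 adjusted over the list alone. Cyba and Lgals3 were higher, by 0.65 ± 0.29 and 0.50 ± 0.28, while C1qa, a complement component of macrophages, was at -0.45 ± 0.34 (adjusted p = 0.094).

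Glucocorticoid-responsive genes had 5 of 15 members higher, 1 lower and 9 not passing, or 6 and 1 adjusted over the list alone. The list mean was 0.48 ± 0.21 (adjusted p = 0.000481, and adjusted p = 0.1 with an estimated correlation), and the median of its members was 0.15. Lcn2, Mt1 and Mt2 also belong to the acute-phase list and Nfkbia to the cytokine list, so this result is not separate from theirs. Sgk1, a kinase of ion transport, was 0.72 ± 0.23 higher and the metallothionein Mt2 1.09 ± 0.54 higher. The lower member was Nr3c1, the glucocorticoid receptor itself, at -0.43 ± 0.14, and Foxo3 was at -0.23 ± 0.22. Mt1, fixed by name, was at 0.86 ± 0.72 and did not pass (adjusted p = 0.0983). Among 18 cardiac stress and hypertrophy markers, 6 were higher, 1 was lower and 11 did not pass, or 8 and 2 adjusted over the list alone (mean 0.27 ± 0.03, adjusted p = 0.00489, and adjusted p = 0.137 with an estimated correlation). Nppb and Sgk1 had the smallest p among its higher members. The lower member was the cardiac transcription factor Gata4, at -0.43 ± 0.26, which passed among genes but not among probes (adjusted p = 0.0673), and the mitophagy receptor Bnip3 was at -0.46 ± 0.49.

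Heat shock and endoplasmic reticulum stress genes were lower as a list. Of 30 heat shock and endoplasmic reticulum stress genes, 9 were lower, 1 was higher and 20 did not pass, or 18 and 1 adjusted over the list alone, with a mean of -0.42 ± 0.12 (adjusted p = 3e-09, and adjusted p = 0.137 with an estimated correlation). In sub-sets formed after the values were seen, 7 of 11 endoplasmic reticulum chaperones and folding enzymes were lower (median -0.58). Of the other 19 members of the list, 2 were lower and 1 was higher (median -0.18). Manf, a secreted factor induced by misfolded protein, was at -1.09 ± 0.20. The higher member was Atf4, a transcription factor of the integrated stress response, at 0.66 ± 0.17 (adjusted p = 0.00876), and Hspb1 was at 0.27 ± 0.47. Of 36 extracellular matrix and fibroblast genes, 5 were lower, 1 was higher and 30 did not pass, or 10 and 1 adjusted over the list alone (mean -0.29 ± 0.13, adjusted p = 0.000177, and adjusted p = 0.251 with an estimated correlation). Sparcl1, a matricellular protein, was at -0.86 ± 0.29 and Serpinh1 at -1.52 ± 0.15, while Igfbp3, which binds insulin-like growth factors, was 0.80 ± 0.15 higher and Col12a1 was at 0.20 ± 0.18.

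The 3 lists of mitochondrial energy genes passed as lower, although most of their members did not pass singly over all genes and no call held with an estimated correlation. Of 20 tricarboxylic acid cycle genes, 5 were lower and 15 did not pass, or 12 lower adjusted over the list alone, with a mean of -0.33 ± 0.10 (adjusted p = 1.34e-07, and adjusted p = 0.1 with an estimated correlation). Sdha, a subunit shared by this cycle and the respiratory chain, was at -0.89 ± 0.20, the ligase subunit Sucla2 at -0.59 ± 0.17 and Sdhc at 0.16 ± 0.22. Of 30 fatty acid genes, 6 were lower, 1 was higher and 23 did not pass, or 7 and 1 adjusted over the list alone (mean -0.20 ± 0.05, adjusted p = 0.000384, and adjusted p = 0.1 with an estimated correlation). The dehydrogenase Acadm was at -0.70 ± 0.18 and Etfdh, which passes electrons to ubiquinone, at -0.50 ± 0.10. Acsl4, which activates long-chain fatty acids, was 0.52 ± 0.04 higher, and the lipid droplet protein Plin2 was at 0.09 ± 0.55. Of 51 oxidative phosphorylation genes, 2 were lower and 49 did not pass, also adjusted over the list alone, and Ndufs1 of complex I was at -0.73 ± 0.31 beside Uqcr11 at 0.19 ± 0.15. This list's mean of -0.15 ± 0.25 (adjusted p = 0.00581, and adjusted p = 0.685 with an estimated correlation) became -0.03 without infected replicate 2, where it did not pass (adjusted p = 0.873).

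Ribosomal protein genes passed as higher (mean 0.05 ± 0.19 over 55 genes, adjusted p = 0.0337, and adjusted p = 0.751 with an estimated correlation), with 0 members passing singly, also adjusted over the list alone. Their mean was -0.04 without infected replicate 4. Rps18 was at 0.46 ± 0.28, Rps25 at 0.23 ± 0.14, Rpl5 at -0.28 ± 0.38 and Rps21 at -0.19 ± 0.28. The sarcomere list of 7 genes did not pass (adjusted p = 0.865), with 0 members passing, also adjusted over the list alone. Pdlim1 was at 0.25 ± 0.11, Tpm3 at 0.37 ± 0.46, Cryab at -0.15 ± 0.16 and Actn2 at -0.16 ± 0.38. The 10 interferon response genes did not pass either (adjusted p = 0.434). Ifitm3, an antiviral membrane protein, was 0.88 ± 0.26 higher, the only member to pass, also adjusted over the list alone, and Tapbp was at 0.30 ± 0.33, Oas1a at -0.37 ± 0.34 and Bst2 at -0.22 ± 0.30.

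The other lists did not pass in infected hearts. Their adjusted p was 0.07 for calcium handling and ion channels, 0.08 for apoptosis regulators, 0.292 for complement and coagulation, 0.292 for endothelial markers, 0.324 for antigen presentation and 0.369 for smooth muscle and pericyte markers. It was 0.424 for proteasome, ubiquitin and autophagy genes, 0.494 for erythrocyte genes, 0.494 for glycolysis, 0.544 for oxidative stress and metal response and 0.566 for the cell cycle. The mean and the median lay on opposite sides of 0 for the interferon and oxidative stress lists, and the sarcomere list was ranked as higher with a mean of -0.01 and a median of -0.11. Mean, median or test also differed in sign for the interferon, cardiac stress, endothelial, proteasome, glucocorticoid, apoptosis and complement lists in uninfected hearts and the oxidative stress and interferon lists for infected minus uninfected, none of which passed there. With an estimated correlation 0 lists passed in any comparison. The estimate lay below the preset 0.01 for the acute-phase (0.00088), cardiac stress (0.0087), fatty acid (-0.0012), glucocorticoid (-0.0017) and cytokine lists (-0.041). For these, correlation between members does not account for the loss, so this setting changed more than the correlation. In the other lists that passed in infected hearts the estimate was higher, up to 0.47 for ribosomal proteins. With camera on ranks the cardiac stress (adjusted p = 0.331), cytokine (0.0688) and neutrophil lists (0.0651) did not pass in infected hearts, and on probes the ribosomal list did not (0.269).

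**Figure D2:**
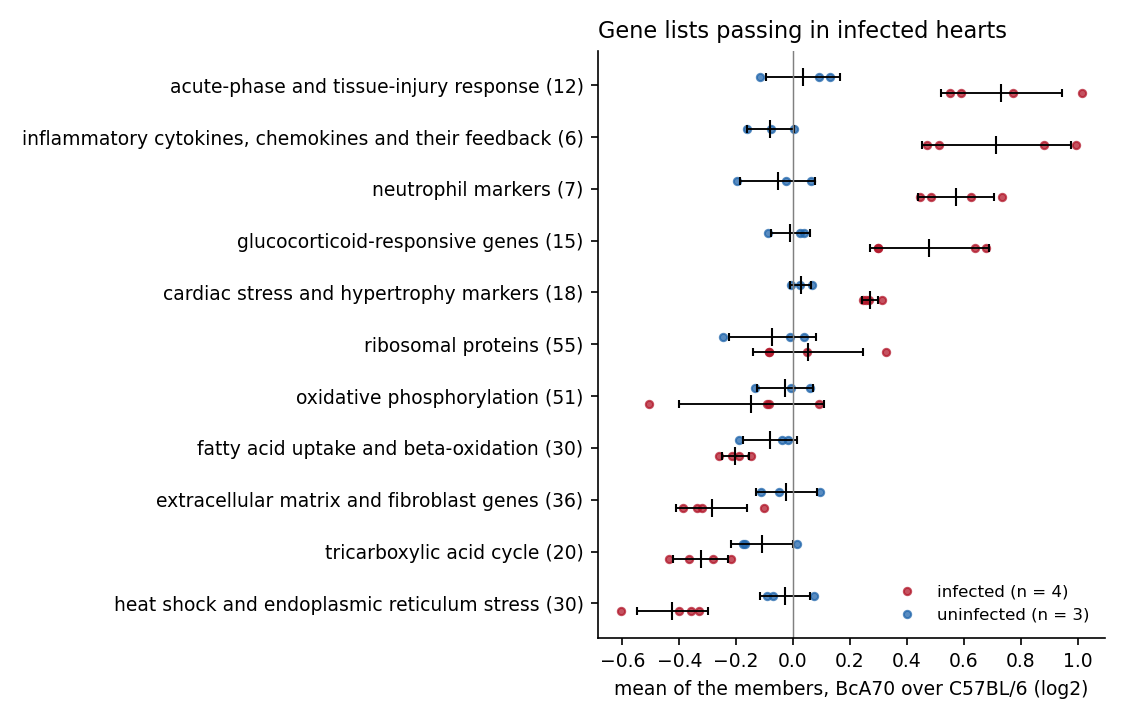
Mean log2 ratio of BcA70 over C57BL/6 of the members of each list (x axis) that passed in infected hearts (y axis, number of measured members in brackets); points are arrays, bars the mean ± SD, red 4 infected and blue 3 uninfected arrays. Acute-phase genes averaged 0.73 in infected and 0.04 in uninfected hearts, and heat shock and endoplasmic reticulum stress genes -0.42 and -0.03.

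Over all 15246 probes, limma called 372 in infected hearts at an adjusted p under 0.05, 192 higher and 180 lower. They covered 106 higher and 118 lower named genes, and 362 of the 372 had the same sign on every array. At an unadjusted p under 0.05 there were 2070 probes against 762.3 by chance. The count was 205 without infected replicate 3, 126 without infected replicate 4, 239 without uninfected replicate 1, 205 with arrays scaled to equal spread, 718 with array weights and 218 with the infected arrays alone. It was 0 with the sign of the Cy3 arrays turned, which makes the mean a contrast of the dyes if the deposited arrays share a direction. Lcn2 did not pass with robust eBayes (adjusted p = 0.0767), with the infected arrays alone (0.0621), or without infected replicate 2 (adjusted p = 0.0551), infected replicate 4 (0.144) or uninfected replicate 1 (0.0518), and of the other named genes, calls were lost on leaving out an array for Nfkbiz, Nr3c1, Lgals3, Acsl4, Atf4, Sucla2, Gja1, Etfdh, Cyba and Ndufs1.

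In uninfected hearts no probe passed, and the values of the genes with the smallest p are given without a call. Nppb was at 1.38 ± 0.38 (n = 3, adjusted p = 0.0913), and Alad, the enzyme of the 2nd step of heme synthesis, at 0.89 ± 0.05 (adjusted p = 0.1). Hba-a1, an alpha globin gene with a near-identical copy that its probes may also detect, was at -1.17 ± 0.40 (adjusted p = 0.108). The other genes with the smallest p and the same sign on every array were Glo1 at 0.70 ± 0.47, Cap1 at 0.71 ± 0.41 and Perp at 0.47 ± 0.10, and, below 0, Clmn at -1.37 ± 0.53, the growth factor Igf1 at -1.24 ± 0.49, the thymidylate synthase Tyms at -1.25 ± 0.43 and Add3 at -1.02 ± 0.43, none of which passed. Of the 3 probes of Igf1, 2 had this sign. The probes of Clmn, Igf1, Tyms and Add3 belonged to a set of 32 with a p under 0.001 and a mean below -0.5, 5 of them for Hba-a1. They correlated with the Hba-a1 profile over the infected arrays at r 0.993, 0.998, 0.907 and 0.785. That profile was at 0.32 on infected replicate 1 and between -0.29 and -0.20 on the others, so each r rests mainly on that array. Genes with large infected differences were near 0 here: Lcn2 was at 0.02 ± 0.26, S100a9 at -0.06 ± 0.37 and Mt2 at 0.03 ± 0.25. Mt1, which did not pass in infected hearts, was at 0.17 ± 0.59.

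As groups, 4 lists were lower in uninfected hearts, although 0 of their members passed singly. Erythrocyte genes averaged -0.15 ± 0.11 over 9 members (adjusted p = 0.013, and adjusted p = 0.137 with an estimated correlation), with Hba-a1 the 1 member lower adjusted over the list alone. Hba-x was at -0.16 ± 0.08, Tfrc at 0.20 ± 0.55 (1 of its 2 probes had this sign) and Rhd at 0.05 ± 0.10. Fatty acid genes averaged -0.08 ± 0.10 (adjusted p = 0.0205, and adjusted p = 0.137 with an estimated correlation), with Oxct1, an enzyme of ketone body use, at -0.95 ± 0.45 (1 of its 2 probes had this sign), Ech1 at -0.32 ± 0.26, Pnpla2 at 0.19 ± 0.47 and Plin2 at 0.13 ± 0.09. Tricarboxylic acid cycle genes averaged -0.11 ± 0.11 (adjusted p = 0.0205, and adjusted p = 0.296 with an estimated correlation), with Got2 at -0.95 ± 0.47, Pcx at -0.17 ± 0.12, Sucla2 at 0.19 ± 0.09 and Sdhc at 0.15 ± 0.29. Ribosomal protein genes averaged -0.07 ± 0.15 (adjusted p = 0.00383, and adjusted p = 0.714 with an estimated correlation), with Rpsa at -0.31 ± 0.34 (5 of its 6 probes had this sign), Rps14 at -0.23 ± 0.20, Rpl7a at 0.16 ± 0.29 and Rpl8 at 0.08 ± 0.38. In these 3 lists 0 members passed adjusted over the list alone. Without uninfected replicate 3, the array of females, the fatty acid (adjusted p = 0.322) and tricarboxylic acid cycle lists (0.201) did not pass and the ribosomal mean was 0.01. Without uninfected replicate 1 the erythrocyte list did not pass (adjusted p = 0.065), nor did the tricarboxylic acid cycle list (0.103), and without uninfected replicate 2 the fatty acid list did not (0.107). With camera on ranks the erythrocyte (adjusted p = 0.107), fatty acid (0.0636) and tricarboxylic acid cycle lists (0.0636) did not pass, and with a dye term the ribosomal list did not (0.195).

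The limma count was 0 of 15246 probes, with 315 at an unadjusted p under 0.05 against 762.3 by chance. The median SD between arrays was 0.153 in uninfected and 0.235 in infected hearts, and the uninfected arrays alone gave 0 probes as well, with 510 at an unadjusted p under 0.05. A dye term in the fit called 14 probes, among them probes of Nppb, Alad, Clmn, Igf1, Tyms and Hba-a1. Array weights called 53, arrays scaled to equal spread 31, and the count was 10 without infected replicate 1, 1 without infected replicate 2 and 4 without uninfected replicate 2.

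The strain difference itself differed between infected and uninfected hearts for 33 probes, among them those of 16 genes named here. The numbers in the sample titles were all higher for uninfected than for infected arrays, and what they count is not stated. If they follow a series of slides, its effect on the ratios cannot be told apart from that of infection in this comparison. Infected minus uninfected was 2.01 ± 0.30 (SE) for Id2, 1.91 ± 0.24 for Cdk8, 1.81 ± 0.28 for Gadd45g, 1.79 ± 0.25 for S100a9 and 1.67 ± 0.14 for Hmox1. It was 1.58 ± 0.24 for Nr5a1, a nuclear receptor of steroid-producing tissue, and 1.56 ± 0.18 for Lilr4b, a receptor of myeloid cells. It was 1.54 ± 0.21 for Hdc, 1.53 ± 0.24 for Socs3 and 1.53 ± 0.19 for Ctla2b, a protease inhibitor-like gene. In the other direction it was -1.85 ± 0.20 for Hsp90b1, -1.52 ± 0.21 for Serpinh1, -1.39 ± 0.19 for Hspa5, -1.23 ± 0.21 for Pdia6, -1.12 ± 0.15 for Manf and -0.84 ± 0.14 for the ubiquitin ligase Nedd4. Adjusted p ran from 0.00125 (Hmox1) to 0.0416 (Nedd4). The infected and uninfected arrays did not overlap for any of these 16 genes, a condition for naming them that all 33 probes met. Id2 and Nedd4 have 2 probes each, and the values above are those of the probe with the smaller p. With the probes averaged, Id2 was at 1.10 (adjusted p = 0.0811) and Nedd4 at -0.50 (0.153), and neither passed. No other gene named for this comparison, here or among the lists below, passed singly among probes: Lcn2 was at 2.13 ± 0.66 (adjusted p = 0.445), Mt2 at 1.06 ± 0.26 (0.211), Mt1 at 0.69 ± 0.36 (0.898) and Nppb at 0.44 ± 0.24 (0.911). Hba-a1, near 0 in infected hearts at -0.18 ± 0.43, was at 0.99 ± 0.25 (adjusted p = 0.232).

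The same 11 lists passed as in infected hearts, each in the same direction. The mean difference was 0.70 for acute-phase genes (adjusted p = 4.79e-07, and adjusted p = 0.0802 with an estimated correlation), where 2 of 12 were higher, or 5 adjusted over the list alone, with F3 at -0.14 and Cp at -0.08. It was 0.79 for cytokine and feedback genes (adjusted p = 1.23e-05, and adjusted p = 0.1 with an estimated correlation), where 1 of 6 was higher, or 3 adjusted over the list alone, and Nfkbiz was at 0.88 ± 0.27. For neutrophil markers it was 0.63 (adjusted p = 4.42e-05, and adjusted p = 0.137 with an estimated correlation), with 3 of 7 higher, or 4 higher and 1 lower adjusted over the list alone, Lyz2 at -0.66 ± 0.18 and Stfa1 at -0.02 ± 0.15. Glucocorticoid-responsive genes had 0.49 (adjusted p = 0.000659, and adjusted p = 0.1 with an estimated correlation), with 1 of 15 higher, or 5 higher and 1 lower adjusted over the list alone. Their median was 0.14. Zfp36, which destabilises cytokine transcripts, was at 0.90 ± 0.20, Nr3c1 at -0.58 ± 0.14 and Foxo3 at -0.15 ± 0.17. Cardiac stress markers had 0.24 (adjusted p = 0.000865, and adjusted p = 0.121 with an estimated correlation), with 1 of 18 higher, or 7 higher and 1 lower adjusted over the list alone. There Sgk1 was at 0.90 ± 0.16 (adjusted p = 0.0532 among probes), Atf3 at 0.94 ± 0.23, Gata4 at -0.49 ± 0.16 and Bnip3 at -0.54 ± 0.26. Ribosomal protein genes had 0.13 (adjusted p = 0.000384, and adjusted p = 0.669 with an estimated correlation), with Rps18 at 0.55 ± 0.18, Rps25 at 0.32 ± 0.15, Rps4x at -0.23 ± 0.18 and Rps21 at -0.14 ± 0.18.

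Heat shock and endoplasmic reticulum stress genes had a mean difference of -0.40 (adjusted p = 8.78e-09, and adjusted p = 0.137 with an estimated correlation), with 4 of 30 lower, or 7 lower and 1 higher adjusted over the list alone, Atf4 at 0.84 ± 0.17 and Hspb1 at 0.17 ± 0.25. Extracellular matrix genes had -0.26 (adjusted p = 0.00086, and adjusted p = 0.296 with an estimated correlation), with 1 of 36 lower, or 4 lower and 1 higher adjusted over the list alone, Col3a1 at -2.05 ± 0.36 (adjusted p = 0.0527), Igfbp3 at 0.77 ± 0.15 and Vim at 0.42 ± 0.24. Tricarboxylic acid cycle genes had -0.21 (adjusted p = 0.000481, and adjusted p = 0.137 with an estimated correlation), with 0 of 20 passing, or 2 lower adjusted over the list alone. There Sucla2 was at -0.78 ± 0.15, Sdha at -0.71 ± 0.18, Got2 at 0.38 ± 0.31 and Pcx at 0.12 ± 0.14. Oxidative phosphorylation had -0.12 (adjusted p = 0.0246, and adjusted p = 0.735 with an estimated correlation), with Ndufs1 at -0.74 ± 0.19, Uqcr11 at 0.24 ± 0.14 and Atp5e at 0.31 ± 0.20. Fatty acid genes had -0.12 (adjusted p = 0.0366, and adjusted p = 0.153 with an estimated correlation), with Acadm at -0.56 ± 0.15, Etfdh at -0.40 ± 0.14, Acsl4 at 0.48 ± 0.13 and Pex11a at 0.57 ± 0.42. Of the ribosomal, oxidative phosphorylation and fatty acid members 0 passed, also adjusted over the list alone. The oxidative phosphorylation list did not pass without infected replicate 2 (adjusted p = 0.795), uninfected replicate 1 (0.0604) or uninfected replicate 2 (0.226), the fatty acid list without the same 3 arrays (0.158, 0.133 and 0.0996), and the ribosomal list without infected replicate 4 (0.307) or uninfected replicate 3 (0.232). With camera on ranks the cardiac stress (adjusted p = 0.0629), neutrophil (0.0636) and fatty acid lists (0.0636) did not pass.

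Over all probes, limma called 33, of which 25 had a higher and 8 a lower strain difference after infection, with 935 at an unadjusted p under 0.05 against 762.3 by chance. All 33 also passed in infected hearts with the same sign. Scaling the arrays to equal spread left 3 probes, 3 higher and 0 lower, so that of the 16 genes only Gadd45g passed and adjusted p of the others, Hmox1 among them, ran from 0.109 to 0.193; array weights gave 142 and turned Cy3 arrays 0. The count was 7 without uninfected replicate 1, 11 without uninfected replicate 2, 11 without uninfected replicate 3 and 87 without infected replicate 2, and of the 16 genes Hmox1, Hsp90b1 and Serpinh1 passed whichever array was left out, though not with scaling.

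**Figure D3:**
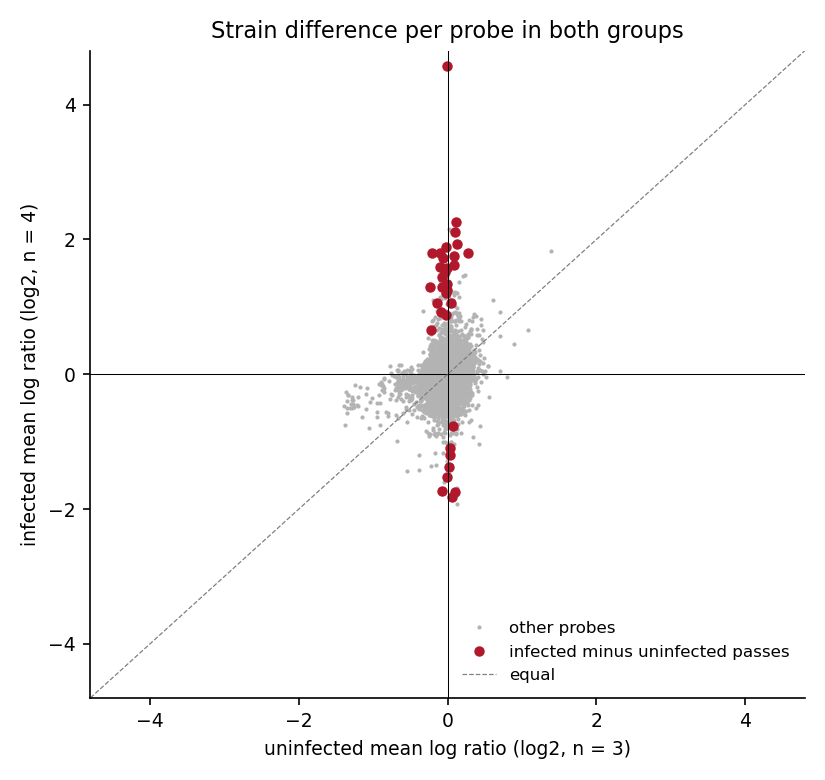
Mean log2 ratio of BcA70 over C57BL/6 of each of 15246 probes in uninfected (x axis, n = 3) and infected hearts (y axis, n = 4); red points are the 33 probes whose infected minus uninfected difference passed, grey points the others, and the dashed line marks equal values. The red points lie near 0 on the x axis and away from 0 on the y axis.

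Strain differences in the infected and uninfected groups, which share no array, correlated weakly across the 15246 probes (Pearson's r 0.207, Spearman's rho 0.182; genes are not independent replicates). The r was 0.128 without uninfected replicate 3, the array of females, and single pairs of an infected and an uninfected array ranged from -0.163 to 0.259. At an unadjusted p under 0.05 in both groups, 22 probes were higher in both and 59 were lower in both; the groups share each probe's estimate of the spread, so these counts have no simple chance level. Nppb was among the genes with an unadjusted p under 0.01 and the same sign in both groups, with Alad, Cap1, Glo1, Maged1 and Plac9b, 6 genes in all. Maged1 and Plac9b, named here after their values were seen, averaged -0.64 ± 0.40 and -0.82 ± 0.50 over all 7 arrays.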

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

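The tests of the 3 patterns below were chosen after the results they concern had been seen, while the count over other groupings of the arrays was planned. In infected hearts 7 of 64 named genes had an array far from the other 3. The rate set for this check was about 1 in 20. These genes share the same arrays and were in part chosen by their values on them, so an excess is not shown. Replicate 1 stood apart for Gadd45g (2.82), Ifitm3 (0.49) and Cyba (1.09), replicate 2 for Vta1 (-0.73) and Mt2 (1.89), replicate 3 for Cxcl12 (0.048) and replicate 4 for S100a9 (2.38).

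The strain difference of 16 genes differed between infected and uninfected hearts by a test of that difference. Infected minus uninfected was 2.01 for Id2, 1.91 for Cdk8, 1.81 for Gadd45g, 1.79 for S100a9, 1.67 for Hmox1, 1.58 for Nr5a1, 1.56 for Lilr4b, 1.54 for Hdc, 1.53 for Socs3 and 1.53 for Ctla2b. It was -1.85 for Hsp90b1, -1.52 for Serpinh1, -1.39 for Hspa5, -1.23 for Pdia6, -1.12 for Manf and -0.84 for Nedd4. With the probes of a gene averaged, Id2 (1.10, adjusted p = 0.0811) and Nedd4 (-0.50, adjusted p = 0.153) did not pass. Of the 35 splits of the 7 arrays into 4 and 3, only the real split (1) called as many as 33 probes, and the highest other called 20. This share is under 0.05 but is the smallest that 35 splits allow, and it holds for the values as deposited. With arrays scaled to equal spread the real split called 3 probes. In infected hearts 1 of 8 sign patterns of the arrays called 372 probes, with 2 as the highest other, and in uninfected hearts 4 of 4 called 0, with 0 as the highest other; these patterns were too few for a share under 0.05.

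Infected replicate 2 stood apart from infected replicate 1 (r -0.119), and its labels name BcA70 for either channel in different fields. If both channels had held BcA70 RNA, its ratios should have been near 0. Over the 551 probes called without it, its slope on the mean of the other infected arrays was 0.506 (SE 0.0285), and 71.1% of them had the same sign. The slope lay above the bound set for this explanation but did not exceed the bound set against it by more than its SE. The test therefore did not decide. A partial mixture cannot be told apart from a weaker response either, since no intensities were available. A dye effect left by the authors' correction is the other candidate explanation. The dye contrasts of the 2 groups correlated at r 0.164, between the bounds of 0.1 and 0.2 set for this test. Once a dye term was removed, the r of replicates 1 and 2 went from -0.119 to 0.263, which met the other part of the prediction. That part decides little. The 2 arrays have opposite dyes and the dye term was estimated in part from them, so removing it raises their r even without a dye effect. A dye effect is therefore left open. A difference between the animals was not tested.

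In uninfected hearts, 32 probes had a p under 0.001 and a mean below -0.5, 5 of them for Hba-a1 and 11 for other single symbols; 30 of the 32 had probe numbers from 10561 to 13609, a span of 3049 of the 15246 probes, where the other probes had a median of -0.011, and an effect of place on the slide or plate was not tested. A dye effect of the size that the infected arrays show was argued against as the whole cause: removing it moved their median from -1.25 to -1.16 (spread 0.206), and with a dye term in the fit Hba-a1 was at -1.11 (adjusted p = 0.0489) and Clmn at -1.27 (0.0265). A larger dye effect peculiar to the uninfected arrays stays open, since the median of -0.71 with BcA70 in Cy3 came from a single array that also served to choose the probes. Binding of globin transcripts by probes of other names may account for part of the set, as may their shared place. Of these probes 76.9% followed the Hba-a1 profile over the infected arrays at r above 0.8, against 13.6% of other probes. The ratio was 5.66 (permutation p = 1e-04, the smallest possible). The profile was 0.32, -0.20, -0.29 and -0.27, so r rests mainly on infected replicate 1, the array with the widest spread (SD 0.425). Probes sharing a place may not be independent, which would make this permutation p too small. Less blood in these hearts stays open, since the erythrocyte genes Alas2, Slc4a1, Rhd, Car1 and Bpgm had a median of -0.04 (spread 0.136) against -0.78 for the mean of the 7 Hba-a1 probes, but their signal over background is unknown and strain variants of the globin genes were not tested.

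Of 11 endoplasmic reticulum chaperones and 11 collagens, sub-sets that were formed after the values had been seen and not tested as groups, 7 and 2 passed as lower in infected hearts, with means of -0.80 ± 0.24 and -0.40 ± 0.17. A dye effect was argued against for the chaperones, whose highest median on any infected array was -0.39. Forming the sub-set after these arrays were seen favours that outcome. The whole heat shock and endoplasmic reticulum stress list, fixed in advance, was below 0 with either dye. Its means were -0.60 and -0.36 with BcA70 in Cy3, and -0.33 and -0.40 in Cy5. For the collagens the highest median was -0.058, which did not decide that test. The dyes were balanced in the infected group, so a dye effect of equal size on each array would cancel in the collagen mean. Only a dye effect that differs between the arrays stays open for them. Fewer fibroblasts in the BcA70 hearts may contribute: the extracellular matrix list had a median of -0.17 and the chaperones -0.58, a gap of 0.42 (bootstrap SD 0.237), which exceeds 1 SD, the bound first set for arguing against it, but not 2 SD, the bound applied after the value was seen, so it was left open. A lower folding load in the cells themselves was not tested.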

How the results depend on the processing

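All alternatives were fixed before the data were examined. No paired analysis was possible because replicate numbers only follow the order of the samples. The probes called in infected hearts (372) numbered 205 with arrays scaled to equal spread, 226 at gene level, 718 with array weights, 218 with only these arrays in the fit and 0 with the Cy3 arrays turned, and 126 to 551 on leaving out an array. The count in uninfected hearts (0) was 31 with scaling, 14 with a dye term, 53 with array weights and 0 to 10 on leaving out an array. The count for infected minus uninfected (33) was 3 with scaling (3 higher, 0 lower), 142 with array weights, 0 with the Cy3 arrays turned and 7 to 87 on leaving out an array. The gene level held fewer tests, and the fit on a group's own arrays used fewer arrays. That fit also used the group's own spread, whose median SD was 0.235 in infected and 0.153 in uninfected hearts. The shared spread may therefore make infected p-values too small and uninfected ones too large. Probes at an unadjusted p under 0.05 went from 2070 to 1629 in infected and from 315 to 510 in uninfected hearts. How far each moved the counts was not tested. For the other settings except the turned arrays the cause was not tested either. Lists passing in infected (11), uninfected (4) and infected minus uninfected (11) numbered 0, 0 and 0 with an estimated correlation, and 8, 1 and 8 with camera on ranks; leaving out an array gave 10 to 12, 1 to 4 and 9 to 13. The correlation between the groups ranged from 0.128 to 0.227 on leaving out an array. Signal over background limits are unknown.

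With scaling F3 in infected hearts was 0.0062, Mt2 and Lcn2 in uninfected hearts -0.0069 and -0.013, and Nppb infected minus uninfected -0.10. With a dye term Mt2 and Lcn2 in uninfected hearts were -0.048 and -0.000965. With array weights F3 and Plin2 in infected hearts were 0.038 and -0.011, and S100a9 in uninfected hearts 0.040. With infected replicates 1 and 2 averaged F3 was 0.0064. These values changed sign, and the cause was not tested. Turning the Cy3 arrays makes a mean a contrast of the dyes if the deposited arrays share a direction. The 372 infected probes called as deposited, against 0 when turned, go with a shared direction in that group. If it is shared, the sign changes and counts of 0 under this setting follow from its construction and say nothing about stability. With them turned, infected values were Gadd45g -0.34, Nppb -0.24, Id2 -0.50, Socs3 -0.32, Hmox1 -0.061, Mir22hg -0.63, S100a9 -0.25, Hdc -0.088, Col3a1 0.51, Vta1 0.31, 4921507G05Rik 0.29, Hspa5 0.17, Gja1 0.56, Pdia6 0.24, Mgp 0.051, Zeb2 0.073, Cp 0.22, F3 0.030, Sgk1 -0.039, Gata4 0.079, Bnip3 0.32, Igfbp3 -0.12, Sparcl1 0.064, Plin2 -0.32, Etfdh 0.062, Foxo3 0.080, Hspb1 -0.38, Nfkbiz -0.38, Cxcl12 0.084, Tapbp -0.065, Cyba -0.12, Lyz2 0.13, C1qa 0.036, Stfa1 0.076, Uqcr11 -0.042, Sdha 0.12, Ndufs1 0.25, Rps18 -0.23, Rps25 -0.021, Tpm3 -0.40. Uninfected values were Rhd -0.056, Sdhc -0.18. Infected minus uninfected values were Id2 -0.17, Gadd45g -0.51, S100a9 -0.16, Hmox1 -0.036, Nr5a1 -0.098, Lilr4b -0.15, Hdc -0.23, Socs3 -0.48, Hsp90b1 0.11, Serpinh1 0.26, Hspa5 0.24, Pdia6 0.29, Nedd4 0.045, Lcn2 -0.16, Mt1 -0.0066, Nppb -0.89, Cp 0.024, Sgk1 -0.043, Atf3 -0.37, Gata4 0.046, Bnip3 0.22, Igfbp3 -0.099, Col3a1 0.85, Acsl4 -0.067, Etfdh 0.13, Foxo3 0.086, Hspb1 -0.54, Nfkbiz -0.27, Lyz2 0.44, Stfa1 0.20, Uqcr11 -0.0018, Atp5e -0.19, Sdha 0.39, Ndufs1 0.33, Rps18 -0.076.

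Ranges on leaving out an array that crossed 0 were, in infected hearts, Cp -0.21 to 0.10, F3 -0.037 to 0.014, Plin2 -0.17 to 0.27, Stfa1 -0.084 to 0.010, ribosomal proteins -0.040 to 0.098. In uninfected hearts they were Lcn2 -0.12 to 0.14, Mt1 -0.098 to 0.48, Mt2 -0.073 to 0.16, Pnpla2 -0.042 to 0.43, Rhd -0.0053 to 0.093, Rpl8 -0.11 to 0.28, S100a9 -0.22 to 0.14, Sdhc -0.017 to 0.24, Tfrc -0.11 to 0.41, ribosomal proteins -0.13 to 0.015. For infected minus uninfected they were Cp -0.27 to 0.043, F3 -0.25 to 0.026, Pex11a -0.15 to 0.96, Stfa1 -0.13 to 0.065.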

Other observations

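The test of neighbouring genes was planned before its result was seen; the genes and probes named here were chosen after their values were seen. In infected hearts Pecam1 and Cav1, genes of endothelial cells, were the members of the endothelial list that passed as lower, at -0.56 and -0.89, while the list did not pass (adjusted p = 0.292). Of 27 oxidative stress genes, 5 were higher, 2 lower and 20 did not pass, or 6 and 4 adjusted over the list alone, and the list did not pass (adjusted p = 0.544, median -0.03). Among those that passed, Txnrd1 and Gsr, which reduce thioredoxin and glutathione, were at 0.72 and 0.61, the iron store gene Fth1 at 0.53, and catalase (Cat) at -0.76. Nfkbia, the inhibitor of NF-kappa B, was at 1.58.

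The probe with the largest infected mean, probe 4870, carried no single gene symbol. It was at 4.57 ± 1.17 in infected (n = 4, adjusted p = 3.71e-05) and -0.0028 ± 0.06 in uninfected hearts (n = 3), a 23.7-fold infected difference if log2, and passed for infected minus uninfected (adjusted p = 0.00432). Probe 7812 was at 2.26 ± 0.39 in infected and 0.12 ± 0.22 in uninfected hearts.

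A hypothesis was that strain differences present in all 7 arrays lie in segments of the A/J genome carried by BcA70, so that neighbouring genes would differ together. Among 6361 genes, 134 pairs within 5 Mb both had a p under 0.01, against 151.4 after shuffling, a ratio of 0.885 (permutation p = 0.87). This result met the outcome that had been set beforehand as going against the hypothesis. The hypothesis was still left open, because the test had little to work with. The 232 genes under that p were chosen by the mean over 7 arrays, to which the 4 infected arrays contribute. Only 6 genes had a p under 0.01 with the same sign in both groups. Nppb, the gene with the largest mean over all 7 arrays among those differing in both groups, was at 1.64 ± 0.44 (adjusted p = 0.00043).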
